A study of Mus musculus with 3 samples.

How the data were processed

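Single-cell RNA was measured in left-ventricular cells of C56Bl6 mice in 3 libraries, 1 per group, each made from 4 pooled samples per the labels. The Control label gives a standard diet for 10 weeks and names no vector. The other libraries come from mice on a High-Fat + L-NAME diet, a combination used to model heart failure with preserved ejection fraction (HFpEF), with an adeno-associated virus (AAV) carrying either a scrambled short hairpin (HFpEF-scr) or a hairpin against FoxO1 (HFpEF-FoxO1-sh). Per the labels, the diet ran for 6 weeks and the vector for 4 weeks in both. Tissue was dissociated enzymatically, a 70 µm strainer took out cardiomyocytes, debris was removed and red blood cells were lysed, per the labels' protocols. These steps can set the share of a cell class.

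The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, made by the authors with Cell Ranger 6.1.2 on the genome build mm10, per the file headers and the submitters' processing notes. The notes name neither the annotation release nor a filter on barcodes, and the lowest UMI total per barcode in every library was 500. The files hold 30360 genes with Ensembl identifiers and symbols, and no cell annotation. Gene positions are on mm10 and counted from 1.

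Barcodes with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5, at an expected rate of 12% and seed 0. Its automatic threshold marked 1.41%, 2.29% and 3.09% of barcodes past the filters in Control, HFpEF-scr and HFpEF-FoxO1-sh. These lay between the set bounds of 0.5% and 30%, so it was used. They are below the expected rate, so unmarked doublets may remain. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes chosen within libraries gave 30 principal components. Cells were joined to 15 nearest neighbours and clustered with the Leiden method (igraph 0.11.9, resolution 1.0, seed 0), with no batch correction. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9 were used.

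Each cluster took the class with the most markers among its top 50 genes by fold, from marker lists of 22 classes, with at least 3 detected markers (a UMI in at least 10% of the cluster's cells). A cluster stayed unnamed where another class had more markers among its top 10 genes. The names therefore mean cells that are like the class by these markers, such as fibroblast-like, and the suffix is left out after the first mention. A pair of steps was added after the clusters were seen. Clusters with fewer than 3 markers against all other cells were compared again with the named cells other than fibroblasts, since fibroblasts are most of the cells. This second pass named 7 clusters, with 41.7% of kept cells in Control, 43.2% in HFpEF-scr and 46.1% in HFpEF-FoxO1-sh. Clusters in which a pair of classes tied were clustered once more on their own. Gene levels were compared in classes with at least 50 kept cells in every library. Shares were compared without that minimum, and rest on 44 neutrophils in Control, 46 mesothelial cells in HFpEF-scr and 43 proliferating cells in HFpEF-FoxO1-sh.

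UMIs were summed per class and library and divided by the class total to give CPM (UMIs of a gene per 1e6 UMIs of the class). Sums carry exact Poisson 95% intervals, shares of cells exact Clopper-Pearson 95% intervals, and ratios of CPM or of shares exact conditional binomial 95% intervals. All of these cover counting error only. Intervals of CPM treat UMIs as independent, although UMIs of the same cell come together. They therefore do not cover the sampling of cells or animals. With 1 library per group there is no replicate check and no test, so no p-value and no count of changed genes over all genes is given. Every comparison compares libraries, not conditions. Counts of higher or lower list members only describe these libraries, and the share of all measured genes past the same rule was not taken.

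The cell filters, markers, 28 gene lists, the classes each list was read in and the rule for named genes were fixed before the data were examined. Of 727 listed genes, 723 were in the files, with older symbols matched through a gene name table. A list member was measured with at least 20 UMIs over both libraries of a comparison, and a list needed at least 5 measured members. The log2 ratio used CPM with a pseudocount of 1. A list's median was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression. It is said to stand apart at a percentile at or under 2.5 or at or over 97.5, as a description of these libraries. A member was counted as higher or lower when its CPM ratio was at least 1.5 either way and its interval excluded 1. From each list, up to 4 members with the largest absolute log2 ratio in the class may be named.

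Named genes are, in each of the 4 classes with the most cells in their smallest library, the 3 highest and 3 lowest log2 ratios of each main comparison. They needed at least 50 UMIs over both libraries, at least 50 CPM in the higher one, and at least 0.25 of the highest CPM of any class there, against free RNA. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, gene models without a name, clone names and the sex genes Xist, Tsix, Ddx3y, Uty, Eif2s3y and Kdm5d were left out. Other X-linked genes were not. Foxo1 is always named.

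HFpEF-scr enters both main comparisons with opposite sign. For the relation between them across genes with at least 50 UMIs in each library, its UMIs were therefore split at random into a pair of parts, 1 for each comparison. The value was taken from 1 split, with a range over 100 splits, beside the mean of 100 simulations of unchanged libraries with independent UMIs. Genes are not independent replicates.

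Alternatives fixed beforehand, 14 in all, were limits of 10% mitochondrial UMIs and of 1000 UMIs, no doublet removal, resolutions of 0.5 and 2.0, each cell classed singly by its markers, thinning of each cell to 1000 UMIs, CPM over genes other than mitochondrial, ribosomal protein and haemoglobin genes, trimmed mean scaling (TMM, written in Python with trims of 30% and 5%), subtraction of free RNA, a pseudocount of 5, minimums of 100 UMIs for a list member and 200 UMIs for the relation across genes, and UMIs left unsplit. A further 5 were chosen after seeing the data: a limit of 50% mitochondrial UMIs, fibroblasts without 1 cluster, each of the 2 macrophage clusters alone, and each named gene without the cell that held most of its UMIs. Free RNA per class was estimated from markers of other classes, at the 0.25 quantile of their ratios and up to a share of 0.5.

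Depth over kept cells was 96154556 UMIs in Control, 103415472 in HFpEF-scr and 118407618 in HFpEF-FoxO1-sh. The steps were tested on simulated data for HFpEF-scr over Control, with 67 genes each at folds of 1.5 and 2, 66 at 4 and 1000 unchanged. In fibroblasts the intervals held the simulated fold for 89.6%, 92.5% and 90.9% of genes in that order and for 95.4% of unchanged genes, and excluded 1 for 100% at every fold. In macrophages they held it for 91.0%, 95.5% and 97.0%, and 95.5% of unchanged genes, and excluded 1 for 91.0% at a fold of 1.5 and 100% at the others. Endothelial cells gave 98.5%, 92.5% and 90.9%, and smooth muscle cells 94.0%, 92.5% and 95.5%. The simulated UMIs were independent counts, so these values do not show how the intervals do where UMIs come together in cells. Of 40 unchanged lists, 0 stood apart in fibroblasts and 3 in each of the other main classes. Lists for neutrophils were left out, since Control held 44 of these cells, and proliferation and cardiomyocyte lists in pericytes had fewer than 5 measured members.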

Results

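Left-ventricular cells of C56Bl6 mice were profiled with droplet-based 3' single-cell RNA sequencing in 3 libraries, each from 4 pooled samples. The Control library came from a standard diet. HFpEF-scr and HFpEF-FoxO1-sh came from a diet with high fat and L-NAME, an inhibitor of nitric oxide synthases, with a scrambled hairpin or a hairpin against FoxO1. There was 1 library per group and so no replicate at any value below. The matrices held 33022 barcodes and 146230530 UMIs in Control, 36179 barcodes and 154385813 UMIs in HFpEF-scr, and 27453 barcodes and 144561934 UMIs in HFpEF-FoxO1-sh. The median mitochondrial share per barcode was 24.6%, 22.1% and 11.7% in that order, and 56.9%, 53.8% and 31.2% of barcodes lay over the limit of 20%. After the filters and the removal of 182, 342 and 537 marked doublets, 12757, 14567 and 16854 cells were kept. Their median depth was 6889, 6520 and 6607 UMIs and their median mitochondrial share 12.9%, 12.6% and 9.32%.

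Kept cells formed 47 clusters, of which 44 took the name of 19 classes. Fibroblast-like cells were the largest class, with 7538, 8315 and 9804 cells in Control, HFpEF-scr and HFpEF-FoxO1-sh. With macrophage-like cells (1093, 1520 and 1983), endothelial-like cells (467, 678 and 551) and smooth-muscle-like cells (407, 366 and 374) they are the 4 main classes, those with the most cells in their smallest library. Endocardial-like cells numbered 585, 432 and 362. The 3 unnamed clusters held 6.16%, 5.66% and 3.95% of kept cells, and the largest of them was led by Wif1 and Cyp2e1. The platelet-like cluster, with a median of 6971 UMIs, and the main erythroid-like cluster, with 8556 UMIs, were as deep as the nucleated classes. The B-cell-like class joined a cluster with a median of 2772 UMIs, which held 49%, 50% and 94.6% of the class, to one with 8040 UMIs and a median doublet score of 0.226. Of the endothelial-like class, 1 cluster held 74.9%, 77.6% and 77.1%. With at least 1000 UMIs per barcode, the other endothelial cluster was led by Rgs5 and Ephx3. It had 4 pericyte markers among its top 50 genes and a median doublet score of 0.140. With the 50% mitochondrial limit a cluster led by Rgs5 and Ephx3 was named pericyte, so endothelial values at that limit also rest on another class make-up.

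The first question is whether FoxO1, the transcription factor that the hairpin targets, was lower in the library that received it. It was not lower over all kept cells. Foxo1 (ENSMUSG00000044167; mm10, chromosome 3, 52268336 to 52353221, plus strand, 3 exons) had 5875 UMIs in Control, 5809 in HFpEF-scr and 7067 in HFpEF-FoxO1-sh, or 61.1 CPM (59.5 to 62.7), 56.2 CPM (54.7 to 57.6) and 59.7 CPM (58.3 to 61.1). The ratio of HFpEF-FoxO1-sh over HFpEF-scr was 1.06 (1.03 to 1.10). A lower level over all kept cells was therefore not seen, and the sample is called the library labelled HFpEF-FoxO1-sh from here on. The labels do not say which cells the vector enters, and cardiomyocytes were strained out before sequencing. These values therefore cannot show whether the hairpin lowered Foxo1 in the cells it entered, and they do not speak against the label.

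By class, the ratio of the library labelled HFpEF-FoxO1-sh over HFpEF-scr was 1.12 (1.07 to 1.17) in fibroblasts, 1.14 (0.905 to 1.45) in macrophages and 1.18 (0.937 to 1.5) in smooth muscle cells, the last being 0.932 with each cell classed singly and 0.828 after thinning to 1000 UMIs. The macrophage ratio was 0.942 with at most 10% mitochondrial UMIs. Endothelial cells went the other way, with 65.7 CPM (58.8 to 73.1) in Control, 80.3 CPM (73.7 to 87.2) in HFpEF-scr and 62.6 CPM (56.0 to 69.8) in the library labelled HFpEF-FoxO1-sh. Their ratio was 0.781 (0.679 to 0.897) against HFpEF-scr, and 1.22 (1.07 to 1.4) for HFpEF-scr over Control. With a limit of 50% mitochondrial UMIs, chosen after seeing the data, these were 0.880 (0.776 to 0.998) and 1.15 (1.03 to 1.28). Endocardial cells, which line the chambers, held 97.7, 125 and 113 CPM, a ratio of 0.902 (0.773 to 1.05) between the last and HFpEF-scr that was 0.567 after thinning and 1.06 with each cell classed singly. In fibroblasts Foxo1 was lower in HFpEF-scr than in Control, at 57.6 against 64.3 CPM (ratio 0.897, 0.854 to 0.941).

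**Figure D1:**
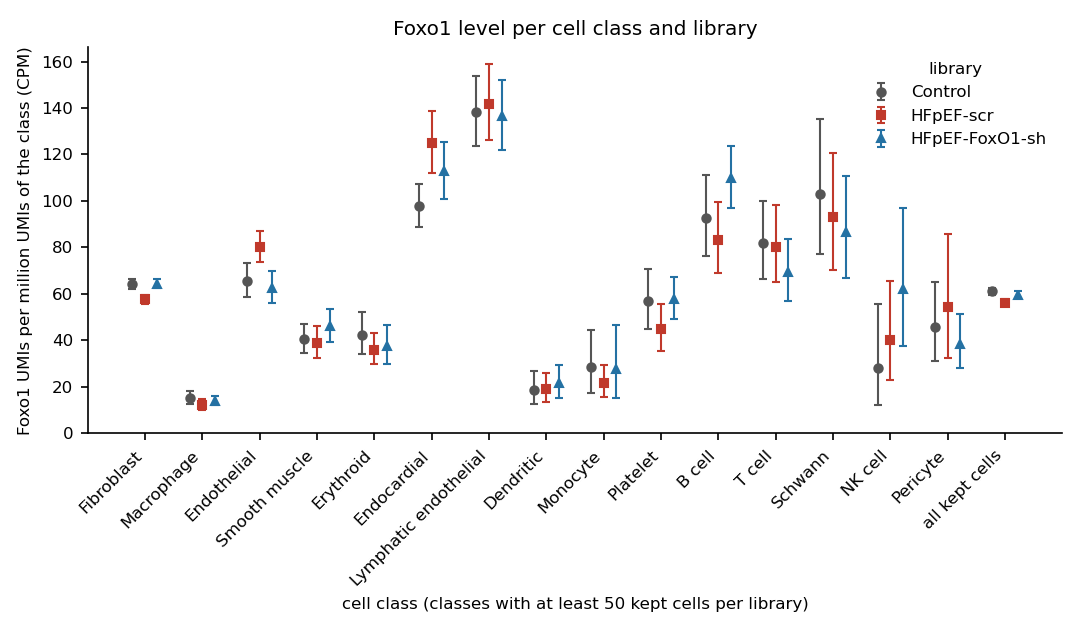
Foxo1 level in CPM of the class (vertical axis) per cell class (horizontal axis) in Control, HFpEF-scr and the library labelled HFpEF-FoxO1-sh; points are pooled libraries and bars exact Poisson 95% intervals. Over all kept cells the 3 libraries lay at 61.1, 56.2 and 59.7 CPM, and endothelial cells were at 80.3 CPM in HFpEF-scr and 62.6 CPM in the library labelled HFpEF-FoxO1-sh.

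HFpEF-scr over Control asks how cells of hearts under the disease diet with the scrambled vector differ from cells of hearts on the standard diet; diet and vector differ together. Monocytes, the blood precursors of many tissue macrophages, made up 1.90% of kept cells in HFpEF-scr and 0.776% in Control, a share ratio of 2.45 (1.94 to 3.11). Macrophages of HFpEF-scr held more RNA of Spp1 (osteopontin), Arg1 and Chil3 and less of the resident genes Lyve1, Timd4 and Fcna. The log2 ratio of Spp1, 1.83, was -0.60 with the 10% mitochondrial limit and -1.12 within the cluster led by Timd4 and Folr2. Fibroblasts had more Ccl2 and Ccl7, chemokines that attract monocytes. Their matrix list stood high, although Col1a1 was level at 1351 against 1343 CPM, and their cholesterol list stood low. Angptl4, an inhibitor of lipoprotein lipase that PPAR factors induce, was higher in fibroblasts, macrophages, endothelial cells and smooth muscle cells of HFpEF-scr.

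Other shares differed as well. Neutrophils were 0.735% of HFpEF-scr and 0.345% of Control cells (ratio 2.13, 1.49 to 3.10), macrophages 10.4% and 8.57% (1.22, 1.13 to 1.32), and proliferating cells 0.982% and 0.596% (1.65, 1.24 to 2.21). Endocardial cells were lower at 2.97% against 4.59% (0.647, 0.570 to 0.734), and so were pericytes, the contractile cells of capillaries, at 0.371% against 0.925% (0.401, 0.285 to 0.558), and mesothelial cells at 0.316% against 0.854% (0.370, 0.256 to 0.526). The pericyte ratio was 0.679 with each cell classed singly. Erythroid cells were higher, at 2.64% against 1.85% (1.42, 1.21 to 1.68). Fibroblasts made up 57.1% and 59.1%. The endothelial share was 4.65% against 3.66% (1.27, 1.13 to 1.43), but with the 50% mitochondrial limit the ratio was 0.926. Of endothelial cells within that limit, 88.3% in Control and 79.1% in HFpEF-scr lay over 20%. The class make-up differed there as well, since a cluster led by Rgs5 with 249 Control and 221 HFpEF-scr cells was named pericyte.

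In fibroblasts the interferon response list stood high, with a median log2 ratio of 0.23 over 39 measured members (percentile 100), 7 of them higher and 0 lower. The chemokine Cxcl10 was at 5.43 against 1.36 CPM (ratio 4.00, 3.09 to 5.25) and the antiviral Rsad2 at 4.35 against 2.20 CPM. Among the fibroblast clusters 1 is led by such genes, Ifit3, Ifit1 and Isg15. Of 26 inflammatory and NF-kB genes 5 were higher and 0 lower (median 0.19, percentile 100). They include Ccl7 with 242 against 88.2 CPM (2.74, 2.65 to 2.84), Lcn2 with 5.59 against 2.13 CPM and Cxcl2 with 6.49 against 2.62 CPM. Ccl2 lay at 266 against 147 CPM (1.81, 1.76 to 1.86). Matrix and activation genes had a median of 0.13 (percentile 100), with Tnc at 8.21 against 4.63 CPM, Postn (periostin) at 186 against 126 CPM and Cilp at 128 against 88.7 CPM, while Comp was lower at 20.0 against 32.9 CPM. Of its 34 members 2 were higher and 1 lower.

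Cholesterol synthesis and uptake genes had the lowest fibroblast median, -0.35 (percentile 0), with 0 of 22 higher and 4 lower. Examples are Fdps (27.2 against 42.5 CPM), Sqle (7.32 against 11.7 CPM) and Idi1 (22.6 against 34.0 CPM). Unfolded protein response genes had a median of -0.13 (percentile 0), with 0 of 26 past the ratio of 1.5, and immediate early genes of -0.08 (percentile 0.02). With at most 10% mitochondrial UMIs the immediate early median was -0.02 and no longer stood apart. Lipid genes had a median near 0 (-0.01, percentile 62.5) over members that went both ways, 5 of 32 higher and 2 lower. Angptl4 was at 71.8 against 24.3 CPM (2.95, 2.77 to 3.14) and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, at 69.2 against 40.3 CPM, with Acot1 lower at 6.99 against 13 CPM. FoxO-regulated genes were close to apart (0.04, percentile 97.4), with Klf15 and Angpt2 the 2 lower members of 33. The other fixed names were all lower: Inmt with 63.6 against 150 CPM (0.424, 0.407 to 0.441), Dhrs3 with 48.4 against 89.2 CPM (0.542, 0.517 to 0.569) and the transcription factor Zbtb16 with 31.3 against 56.5 CPM. RNA of other cells moved too, as haemoglobin Hbb-bs was at 128 against 77.1 CPM and cardiomyocyte transcripts had a median of -0.21 (percentile 0), and erythrocyte and neutrophil transcripts of 0.32 (percentile 100), the last being -0.07 with the 10% limit. TGF-beta response, oxidative phosphorylation, glycolysis, oxidative stress, senescence, insulin signalling, proliferation and cardiac rhythm genes did not stand apart in fibroblasts, with medians from -0.05 to 0.06.

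In macrophages, 9 of 25 monocyte-derived and lipid-associated genes were higher and 1 lower (median 0.46, percentile 100). Spp1 was at 192 against 53.5 CPM (3.59, 3.23 to 4.00), the arginase Arg1 at 6.43 against 0.902 CPM, Chil3 at 7.33 against 1.68 CPM and Fabp5 at 217 against 105 CPM. Of 20 resident genes 0 were higher and 4 lower (median -0.28, percentile 0), namely Fcna (93.3 against 191 CPM), Timd4 (77.8 against 144 CPM), Ccl24 (307 against 564 CPM) and Lyve1 (379 against 652 CPM). Lipid genes had 8 of 29 members higher and 0 lower (median 0.18, percentile 100), among them Angptl4 (7.83 against 1.68 CPM), Pdk4 (3.21 against 0.387 CPM) and Slc27a1 (27.8 against 9.15 CPM), and the lipid droplet protein Plin2 lay at 291 against 168 CPM (1.73, 1.62 to 1.85). Inflammatory genes had a median of 0.09 (percentile 99.1), with Il1rn and Osm the 2 higher of 29, but it was -0.09 within the cluster led by H2-Eb1 and Cx3cr1. The oxidative stress median was 0.10 (percentile 99.5), but -0.04 with the 10% mitochondrial limit. The senescence list had a median of 0.14 (percentile 100) and includes Gdf15, a stress-induced cytokine, with 127 against 72.6 CPM (1.75, 1.59 to 1.94). Interferon genes were lower, with a median of -0.12 (percentile 0.14) and 5 of 39 lower, such as Cxcl9 (17.2 against 46.4 CPM), Gbp2 (12.8 against 23.7 CPM) and Iigp1 (22.0 against 38.3 CPM). Within the cluster led by Timd4 and Folr2 the interferon median was near 0 (0.0023). Unfolded protein response (-0.11, percentile 0.43), cholesterol (-0.15, percentile 2.39), proliferation (-0.24, percentile 0.1) and cardiac rhythm genes (-0.24, percentile 1.61) stood low, and glycolysis genes high (0.11, percentile 99.7), the last with a median of -0.01 within the cluster led by Timd4 and Folr2. After thinning to 1000 UMIs the cholesterol, proliferation and senescence medians were 0.01, 0.27 and -0.10. FoxO-regulated, MHC class II, oxidative phosphorylation, insulin signalling, immediate early and cardiomyocyte genes did not stand apart, with medians from -0.14 to 0.03. Among the other fixed names Cxcl13 was at 78.9 against 240 CPM (0.329, 0.302 to 0.358), with UMIs in 44 Control and 51 HFpEF-scr cells, Mmp9 at 26.1 against 77.1 CPM and Cd209f at 60.9 against 150 CPM. Within the cluster led by H2-Eb1 and Cx3cr1 the log2 ratios of Cxcl13, Mmp9 and Cd209f, -1.59, -1.53 and -1.29, were -0.15, -0.90 and -0.24. With the 10% limit Cxcl13 was at -3.82, Mmp9 at -2.38 and Gdf15 at 1.47 against 0.80.

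Different clusters held most macrophages. The cluster led by Timd4 and Folr2 held 56.6% of them in Control and 47.2% in HFpEF-scr, and the cluster led by H2-Eb1 and Cx3cr1 held 43.4% and 52.8%. In alternatives chosen after seeing the data, the monocyte-derived median was 0.12 within the first and 0.49 within the second, and the resident median was -0.14 and -0.02. Spp1 RNA came from 49 Control and 105 HFpEF-scr cells, and its log2 ratio was 0.24 at resolution 2.0. Haemoglobin Hbb-bs was at 1147 CPM in macrophages of HFpEF-scr and 172 CPM in Control, and the erythrocyte and neutrophil list had a median of 2.37, which was -0.63 with the 10% limit.

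In endothelial cells, lipid genes were higher, with a median of 0.21 (percentile 100), 4 of 30 higher and 0 lower. The fatty acid translocase Cd36 was at 4406 against 2501 CPM (1.76, 1.73 to 1.80), Angptl4 at 44.6 against 13 CPM (3.43, 2.62 to 4.54) and Cpt1a at 51.2 against 31.2 CPM. Apold1 (141 against 76.3 CPM), Btnl9 (600 against 332 CPM) and the retinol-binding protein Rbp7 (654 against 367 CPM) were higher. Cd36, Btnl9 and Rbp7 are also among the markers by which this class was named. Their CPM therefore also depends on how much RNA of other cells the class held, and the estimated share of free RNA, given below, was higher in Control. The retinoic acid hydroxylase Cyp26b1 was lower at 22.1 against 159 CPM (0.139, 0.116 to 0.166), as was Rnaset2a (32.6 against 51.5 CPM), and the growth factor Pgf lay at 38.3 against 54.8 CPM. With the 10% limit Cyp26b1 was among the top 10 genes of the endocardial cluster, a class with a higher share in Control. Its endothelial level may therefore include endocardial RNA. Of 8 MHC class II genes 1 was higher and 6 lower (median -1.16, percentile 0), such as Ctss (3.74 against 19.7 CPM) and Cd74 (78.0 against 211 CPM). Free RNA was estimated at 19.7% of endothelial UMIs in Control and 8.99% in HFpEF-scr, and with the 50% limit the MHC class II median was 0.68. TGF-beta response genes had a median of 0.13 (percentile 99.3), with Tgfbi and Bambi lower, and cardiac rhythm genes of 0.15 (percentile 99.1), which was 0.06 with a minimum of 100 UMIs and -0.13 after thinning. Cholesterol (-0.20), oxidative phosphorylation (-0.06), senescence (-0.11) and proliferation (-0.28) medians stood low, but with the 50% limit they were 0.11, 0.01, 0.07 and 0.02. Nitric oxide and cGMP genes did not stand apart (percentile 40.3), and neither did angiogenesis genes (0.09, percentile 97.0) and adhesion and coagulation genes (0.12, percentile 96.3). FoxO-regulated, inflammatory, interferon, unfolded protein response, glycolysis, oxidative stress, insulin signalling, immediate early and cardiomyocyte genes lay between -0.06 and 0.10 without standing apart. The erythrocyte and neutrophil list was at -0.17 (percentile 1.72), and 0.70 with the 50% limit.

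Smooth muscle cells of HFpEF-scr held more thrombospondin Thbs1, at 372 against 156 CPM (2.38, 2.16 to 2.62). Actc1, a sarcomeric actin, was at 93.9 against 11.4 CPM (8.26, 6.07 to 11.5), with UMIs in 37 and 19 cells, and its log2 ratio of 2.94 was 0.98 with the 10% limit, where Thbs1 was at 2.32 against 1.25. Igfbp3 (45.5 against 89.7 CPM), Rasd1 (42.6 against 73.8 CPM) and Stbd1 (98.2 against 166 CPM) were lower. Neutrophil and red cell RNA in this class differed as well, with S100a8 at 0.242, 91.3 and 66.0 CPM in Control, HFpEF-scr and the library labelled HFpEF-FoxO1-sh, S100a9 at 0.726, 137 and 71.9 CPM and Hbb-bs at 5081, 8699 and 2644 CPM. The log2 ratio of Igfbp3, -0.96, was 0.25 with each cell classed singly, and that of Rasd1, -0.78, was -1.95 with the 10% limit. Cluster 26 held most smooth muscle cells in Control and cluster 14 in the others. In pericytes, of 11 inflammatory genes 3 were higher and 0 lower (median 0.35, percentile 99.7), with Ccl2 at 230 against 29.6 CPM, and contractile genes had a median of 0.31 (percentile 99.8), with Tagln at 755 against 45.9 CPM and Acta2 at 655 against 66.6 CPM. With each cell classed singly the contractile median was -0.12. Those 54 HFpEF-scr and 118 Control pericytes also had high immediate early (0.19, percentile 98.9) and interferon (0.30, percentile 98.7) medians, the former being -0.04 after thinning, and Hbb-bs at 29398 and 18242 CPM, Cd74 at 136 and 4.44 CPM (45 and 3 UMIs) and Col1a1 at 637 and 453 CPM. Their other lists lay between -0.34 and 0.15 and did not stand apart, except erythrocyte and neutrophil transcripts (0.66, percentile 99.9). T cells had 5 of 19 activation genes higher and 0 lower (median 0.28, percentile 100), such as Ccl4 (55.2 against 14.4 CPM) and the checkpoint receptors Pdcd1 (24.3 against 7.62 CPM) and Ctla4 (45.2 against 15.2 CPM). RNA of other cells in T cells differed as well, with Hbb-bs at 3731 against 2011 CPM, Cd74 at 145 against 416 CPM and Col1a1 at 101 against 198 CPM. Activation genes in natural killer cells (0.03, percentile 93.4) and B cell genes (-0.01, percentile 60.3) did not stand apart.

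Over the 77 pairs of a list and a class, 20 stood apart high and 16 low, against 1.925 on each side for random lists. Random lists hold genes drawn without relation to each other, while the pairs share libraries, classes and some genes. The excess over 1.925 therefore does not measure a difference between conditions. With the 10% mitochondrial limit, 35 pairs could be read and 10 stood high and 7 low.

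The library labelled HFpEF-FoxO1-sh over HFpEF-scr asks what the hairpin against FoxO1 does under the same diet, with the reservation that Foxo1 was not lower in it over all kept cells. The monocyte share was 0.498% against 1.90% (ratio 0.262, 0.203 to 0.336), and lay below the 0.776% of Control as well (ratio 0.642, 0.474 to 0.868). Macrophages held less Spp1, Arg1 and Fabp5 and more Fcna, Timd4 and Lyve1, although Spp1 turned to a log2 ratio of 0.87 within the cluster led by Timd4 and Folr2, and fibroblasts had less Postn and Ccl7. The fibroblast matrix list stood low, although Col1a1 was level at 1326 against 1351 CPM. The immediate early list stood high in fibroblasts, and so did the FoxO-regulated list, although none of its members was higher by the ratio of 1.5. The endothelial peptide Edn1, a vasoconstrictor, was higher.

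Proliferating cells were 0.255% against 0.982% (0.260, 0.180 to 0.368), endothelial cells 3.27% against 4.65% (0.702, 0.627 to 0.787) and endocardial cells 2.15% against 2.97% (0.724, 0.628 to 0.835). Macrophages were 11.8% against 10.4% (1.13, 1.05 to 1.21), neutrophils 0.641% against 0.735% (0.872), and fibroblasts 58.2% against 57.1%. B cells were 4.4% against 1.69% (2.61, 2.25 to 3.02), but with the 50% mitochondrial limit the ratio was 0.868 (0.799 to 0.943), since 32.1% of B cells within that limit lay over 20% in the library labelled HFpEF-FoxO1-sh and 89.7% in HFpEF-scr. Pericytes were 1.84% against 0.371% (4.96, 3.71 to 6.75). The ratio was 1.4 with each cell classed singly and 1.56 (1.39 to 1.75) with the 50% limit, where the class also took in a cluster with endothelial markers. Erythroid cells were 1.42% against 2.64% (0.540, 0.458 to 0.636). The monocyte ratio was 0.260 and the neutrophil ratio 0.479 with the 50% limit. With the 10% limit the ratios were 0.502 for B cells, 0.330 for endothelial cells, 1.98 for macrophages and 0.165 for proliferating cells, the last being 0.490 with each cell classed singly.

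**Figure D2:**
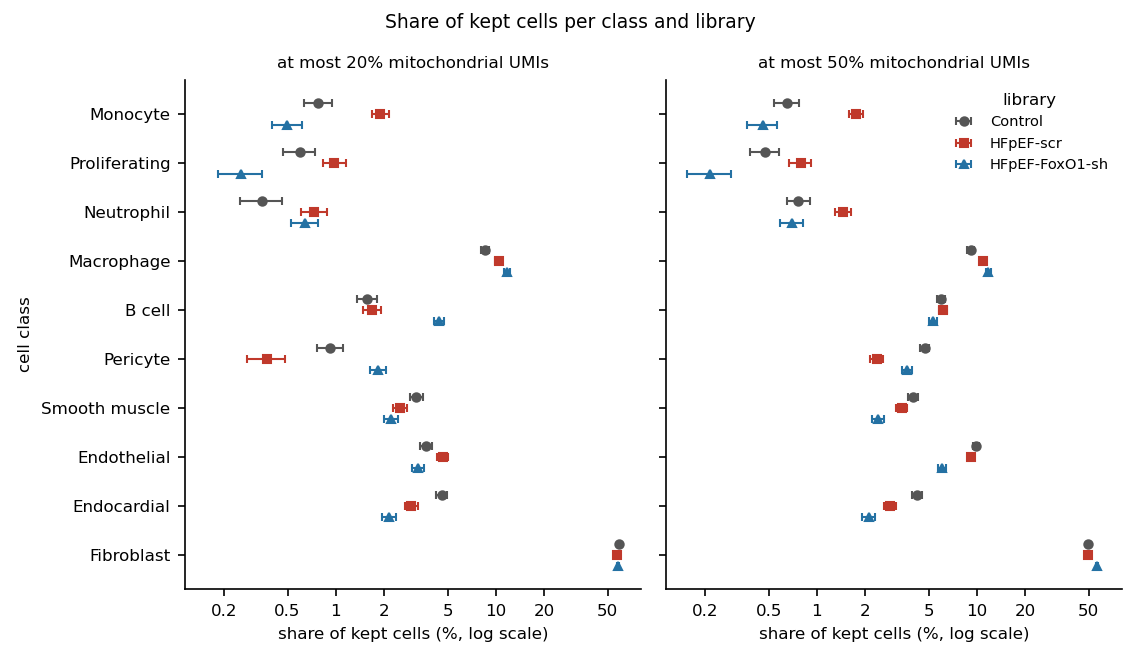
Share of kept cells (%, log scale, horizontal axis) of 10 classes (vertical axis) in Control, HFpEF-scr and the library labelled HFpEF-FoxO1-sh, with at most 20% (left) and at most 50% (right) mitochondrial UMIs; bars are exact Clopper-Pearson 95% intervals. Monocytes lay at 0.776%, 1.90% and 0.498% with the 20% limit, and the B cell share ratio of the library labelled HFpEF-FoxO1-sh over HFpEF-scr was 2.61 with the 20% limit and 0.868 with the 50% limit.

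The largest fibroblast cluster was another in each library, cluster 2 in Control, 1 in HFpEF-scr and 8 in the library labelled HFpEF-FoxO1-sh, with 21.2%, 18.2% and 15.4% of the class. In fibroblasts, immediate early and dissociation stress genes had a median of 0.39 (percentile 100), with 9 of 33 higher and 0 lower. Socs3, a feedback inhibitor of cytokine signalling, was at 130 against 57.1 CPM (2.27, 2.18 to 2.37), Atf3 at 71.5 against 39.9 CPM, Fosb at 289 against 179 CPM and Ier5 at 106 against 66.5 CPM. Among the fibroblast clusters 1 is led by Cxcl1, Il6 and Tnfaip6. It held 11.2% of the class against 4.10% in HFpEF-scr, and without it, an alternative chosen after seeing the data, the median was 0.20. FoxO-regulated genes stood high (0.16, percentile 100), although none of 33 was higher by 1.5 and 1 was lower. Txnip, which restrains glucose uptake, was at 769 against 524 CPM (1.47, 1.45 to 1.49), Cited2 at 76.4 against 53.5 CPM and the cyclin Ccnd1 at 130 against 190 CPM. Foxo1 itself was 1.12 times as high in these fibroblasts, so the hairpin's direction cannot be read from this list.

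Matrix genes had a fibroblast median of -0.18 (percentile 0), with 0 of 34 higher and 4 lower, including Thbs4 (7.71 against 14 CPM), Fmod (2.83 against 5.30 CPM) and Postn (113 against 186 CPM; 0.606, 0.589 to 0.625), while Cilp lay at 89.9 against 128 CPM. The basement membrane collagen Col4a5 (69.3 against 115 CPM), Cst6 (38.1 against 63.1 CPM) and Fndc1 (161 against 248 CPM; 0.650, 0.634 to 0.666) were the fixed names that were lower, and the log2 ratio of Cst6, -0.71, was -1.34 with the 10% limit. Cardiac rhythm genes had a median of -0.10 (percentile 0.08), with Ankrd1 and Sln among 4 of 22 lower, both below 5 CPM, and TGF-beta response genes of -0.05 (percentile 0.22). Oxidative stress genes stood high (0.13, percentile 100), with Gpx3 at 1177 against 709 CPM and the metallothioneins Mt2 (123 against 86.0 CPM) and Mt1 (467 against 332 CPM), and so did lipid genes (0.14, percentile 100), with Angptl4 at 119 against 71.8 CPM and Acot1 at 12.8 against 6.99 CPM. Unfolded protein response genes had a median of 0.11 (percentile 99.5), with Sdf2l1 at 51.3 against 34.0 CPM, interferon genes of 0.09 (percentile 98.0), and glycolysis genes of 0.11 (percentile 99.1), which was -0.06 with the 10% limit. Inflammatory genes did not stand apart (0.05, percentile 62.4) and went both ways, with Il6 at 13.2 against 7.95 CPM, Ccl8 at 11.3 against 18.4 CPM and Ccl7 at 160 against 242 CPM (0.662, 0.646 to 0.679). Cholesterol genes did not either (0.07, percentile 76.1). The methyltransferase Inmt was at 181 against 63.6 CPM (2.84, 2.74 to 2.95) and the complement component C7 at 54.8 against 24.3 CPM (2.25, 2.12 to 2.4). Hbb-bs was at 67.8 against 128 CPM, and the erythrocyte and neutrophil list at -0.84 (percentile 0). Oxidative phosphorylation, senescence, insulin signalling, proliferation and cardiomyocyte genes lay between -0.02 and 0.07 without standing apart.

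In macrophages, interferon genes stood high (0.32, percentile 100), with 7 of 39 higher and 1 lower. Ifit3b (7.58 against 3.11 CPM), Ifit1 (18.8 against 8.94 CPM) and Ifit3 (30.4 against 16.8 CPM) were higher, and Cxcl9 was lower at 1.15 against 17.2 CPM. Resident genes had 3 of 20 higher and 1 lower (0.23, percentile 100), with Fcna at 189 against 93.3 CPM (2.02, 1.88 to 2.19), Timd4 at 140 against 77.8 CPM (1.80, 1.65 to 1.96), Lyve1 at 594 against 379 CPM and the complement receptor Vsig4 lower (0.628, 0.586 to 0.672). The cluster led by Timd4 and Folr2 held 51.8% of macrophages against 47.2%, and that led by H2-Eb1 and Cx3cr1 48.2% against 52.8%. Within the latter the resident median was -0.04. Monocyte-derived and lipid-associated genes had 0 of 25 higher and 7 lower (-0.29, percentile 0), such as Arg1 (0.996 against 6.43 CPM), Gpnmb (9.57 against 30.6 CPM), Spp1 (65.3 against 192 CPM; 0.340, 0.313 to 0.369) and Fabp5 (79.9 against 217 CPM). Within the cluster led by Timd4 and Folr2 that median was -0.03 and the log2 ratio of Spp1 was 0.87, against -1.54 in all macrophages, and with the 10% limit it was -0.29. Lipid genes did not stand apart (0.01, percentile 26.7) and Plin2 was at 309 against 291 CPM. Immediate early genes had a median of 0.24 (percentile 100), with the chaperone Dnajb1 at 238 against 157 CPM. Inflammatory genes did not stand apart (0.02, percentile 42.4), with Saa3 at 35.4 against 3.31 CPM, Il1b at 240 against 140 CPM and Ccl8 at 174 against 342 CPM (0.509, 0.482 to 0.537). The log2 ratio of Ccl8, -0.97, was -2.29 within the cluster led by H2-Eb1 and Cx3cr1. Glycolysis genes had a median of -0.15 (percentile 0), with Vegfa at 1.15 against 4.32 CPM, but it was 0.05 at a resolution of 2.0. Bmp2 was at 62.6 against 30.7 CPM (2.04, 1.78 to 2.33). Hbb-bs was at 199 against 1147 CPM, the erythrocyte and neutrophil list was at -2.25 (percentile 0), and the cardiomyocyte list stood high (0.27, percentile 99.8). FoxO-regulated (0.10, percentile 97.2), MHC class II (0.13, percentile 97.3), unfolded protein response, cholesterol, oxidative phosphorylation, oxidative stress, senescence, insulin signalling, proliferation and cardiac rhythm genes did not stand apart, with medians from -0.04 to 0.14.

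**Figure D3:**
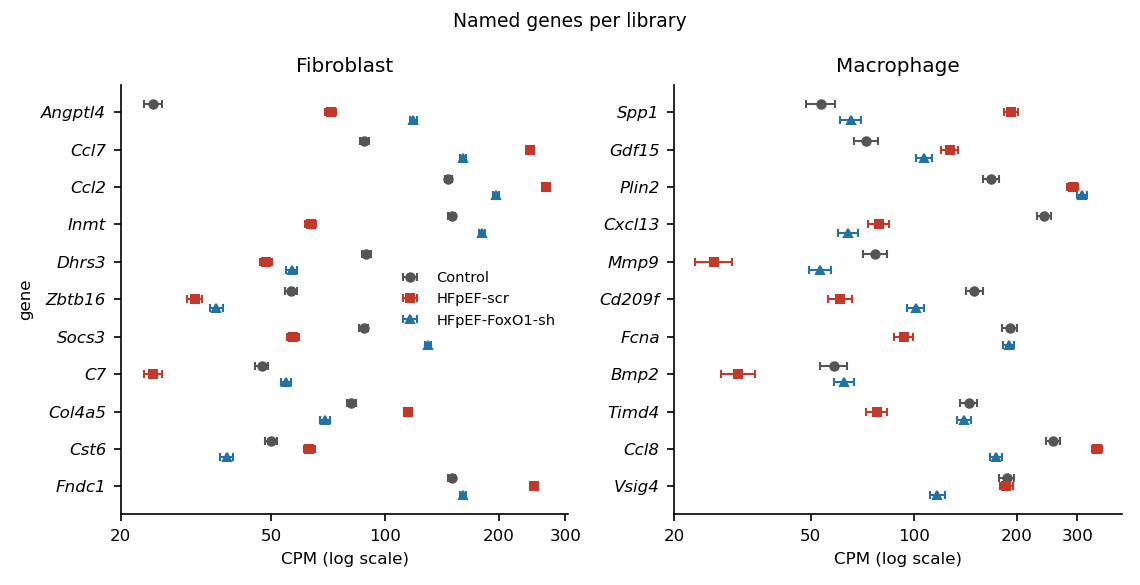
Level in CPM (log scale, horizontal axis) of the named genes of fibroblasts (left) and macrophages (right) in Control, HFpEF-scr and the library labelled HFpEF-FoxO1-sh; points are pooled libraries and bars exact Poisson 95% intervals. Spp1 in macrophages was at 53.5, 192 and 65.3 CPM, and Inmt in fibroblasts at 150, 63.6 and 181 CPM.

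In endothelial cells, angiogenesis genes stood low (-0.12, percentile 0.03), with 2 of 30 higher and 1 lower. Plvap was at 5.01 against 9.78 CPM, the apelin receptor Aplnr at 88.5 against 131 CPM (0.678, 0.604 to 0.759), and Pgf higher at 57.6 against 38.3 CPM. Edn1 (endothelin) was at 165 against 102 CPM (1.61, 1.46 to 1.78), while its nitric oxide and cGMP list did not stand apart (-0.01, percentile 41.1). Cardiac rhythm genes had a median of -0.14 (percentile 0.48), with Ankrd1 and Sln the 2 lower of 21, and -0.08 with a minimum of 100 UMIs. Cholesterol genes were at -0.10 (percentile 1.78), which was 0.05 after thinning, and interferon genes at -0.07 (percentile 2.35), which was 0.03 with the 50% limit. MHC class II genes were high (0.40, percentile 100), with Ctss at 13.3 against 3.74 CPM, while free RNA was estimated at 14.9% against 8.99%. Oxidative phosphorylation (0.08, percentile 99.9), unfolded protein response (0.10, percentile 98.2) and immediate early genes (0.08, percentile 99.6) stood slightly high, the last with Fosb at 127 against 82.0 CPM, and after subtraction of free RNA the latter 2 medians were -0.01 and near 0 (-0.00). FoxO-regulated genes did not stand apart (0.01, percentile 46.1) in the class where Foxo1 was lower. TGF-beta response, inflammatory, lipid, glycolysis, adhesion, oxidative stress, senescence, insulin signalling, proliferation, cardiomyocyte and erythrocyte lists lay between -0.06 and 0.15 without standing apart. Mest (37.6 against 63.1 CPM), the protease Adamts9 (52.0 against 83.0 CPM) and Jarid2 (44.7 against 69.6 CPM) were lower and Prg4 higher (132 against 71.2 CPM). The log2 ratio of Prg4, 0.88, was 0.22 with the 50% limit, that of Mest, -0.73, was -0.13 after thinning to 1000 UMIs, and that of Edn1, 0.68, was 2.04 with the 10% limit. Timp1 was at 52.0 against 22.3 CPM, but 81.1% of its UMIs lay in 1 cell, and without the top cell of each library its log2 ratio of 1.19 was -0.62.

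Smooth muscle cells of the library labelled HFpEF-FoxO1-sh held less Thbs1 (175 against 372 CPM; 0.471, 0.428 to 0.519), Actc1 (12.9 against 93.9 CPM) and Atp13a3 (33.4 against 56.2 CPM), and more Igfbp3 (129 against 45.5 CPM; 2.83, 2.35 to 3.41), Sfrp2 (58.4 against 26.2 CPM) and the tubulin Tubb4b (107 against 64.8 CPM). With each cell classed singly the log2 ratios of Igfbp3 and Sfrp2, 1.48 and 1.13, were -0.02 and -0.55, and with the 10% limit that of Atp13a3 was 0.09 and that of Actc1 -0.04. In pericytes, 310 against 54 cells, inflammatory (-0.43, percentile 0.11) and immediate early genes (-0.20, percentile 0.54) stood low, with Ccl7 at 9.38 against 99.7 CPM and Ccl2 at 46.9 against 230 CPM, and oxidative phosphorylation genes high (0.35, percentile 99.9). The immediate early median was 0.10 with each cell classed singly and 0.01 without doublet removal. Contractile genes went both ways (0.10, percentile 65.8), with Tagln at 9.38 against 755 CPM and the potassium channel Kcnj8 at 3032 against 1078 CPM, and Hbb-bs was at 8871 against 29398 CPM and Cd74 at 19.6 against 136 CPM, with the erythrocyte and neutrophil list at -1.68 (percentile 0). Other pericyte lists lay between -0.11 and 0.45. Natural killer cells had 4 of 15 activation genes higher and 1 lower (0.42, percentile 100), such as Prf1 (perforin, 563 against 247 CPM) and Gzma (7532 against 3962 CPM), and T cells did not stand apart (-0.03). The largest natural killer cluster was cluster 38 in Control, 37 in HFpEF-scr and 39 in the library labelled HFpEF-FoxO1-sh, with 37.3%, 43.1% and 39.5% of 51, 72 and 76 cells. At the 50% limit the class was a cluster of 1362 cells that held T cell markers as well, and its median was 0.03. B cell genes stood high (0.62, percentile 100), with Cd83 at 414 against 199 CPM, while the deeper cluster made up much less of the class in this library, and the median was 0.01 with the 50% limit. Free RNA was estimated at 6.66% of B cell UMIs against 30%, with Hbb-bs at 7308 against 28433 CPM and Col1a1 at 81.8 against 583 CPM.

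The 77 pairs of a list and a class gave 18 high and 14 low. With the 10% mitochondrial limit, 10 of 37 were high and 10 low.

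Across genes, the log2 ratios of both comparisons ran in opposite directions. With the HFpEF-scr UMIs split, Spearman's correlation was -0.446 over 12025 genes in fibroblasts, -0.273 over 8458 in macrophages, -0.367 over 8105 in endothelial cells and -0.240 over 6482 in smooth muscle cells. Simulated unchanged libraries gave 0.00466, 0.00276, -0.00537 and 0.0225. The covariance was -0.0141, -0.0180, -0.0265 and -0.0169, against simulated values of 7.45e-05, 0.000186, -0.000314 and 0.00142. Unsplit, the correlations were -0.625, -0.566, -0.619 and -0.587, where unchanged libraries gave -0.479, -0.464, -0.414 and -0.485. A deviation of the HFpEF-scr library as a whole remains shared by both comparisons after the split and cannot be told from an effect with 1 library per group.

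**Figure D4:**
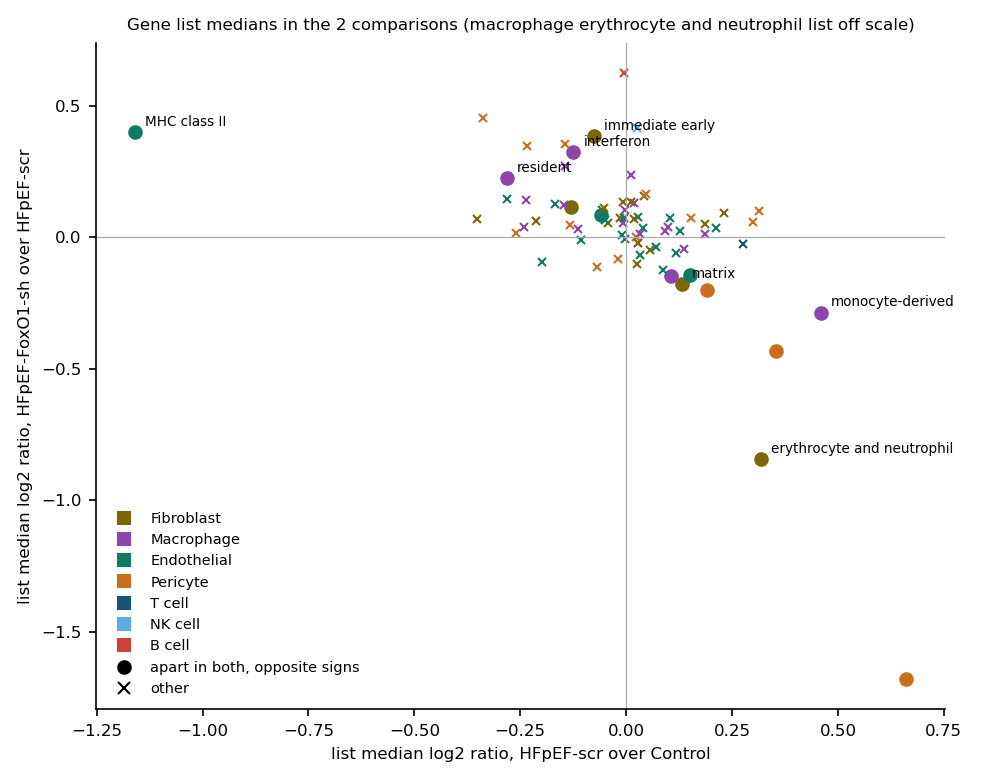
Median log2 CPM ratio of each gene list in each class it was fixed for, HFpEF-scr over Control (horizontal axis) against the library labelled HFpEF-FoxO1-sh over HFpEF-scr (vertical axis); circles are lists that stood apart in both with opposite signs. The same HFpEF-scr UMIs enter both axes with opposite sign, and no values of unchanged libraries were taken for the medians. The monocyte-derived list of macrophages lies at 0.46 and -0.29, and the matrix list of fibroblasts at 0.13 and -0.18.

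The library labelled HFpEF-FoxO1-sh over Control shows how far that library stood from the standard diet. Some differences of HFpEF-scr were present in it too. The same Control library enters both comparisons, so a deviation of Control alone would also give shared differences and cannot be told apart here. Fibroblast interferon genes (0.34, percentile 100, 9 of 39 higher) and inflammatory genes (0.23, percentile 100) stood high and cholesterol genes low (-0.24, percentile 0). Endothelial lipid genes (0.23, percentile 100) and macrophage lipid genes (0.15, percentile 100) were high, with Angptl4 at 119 CPM in fibroblasts against 24.3 CPM in Control. Fibroblast matrix genes were near 0 with a low percentile (-0.02, percentile 0), and macrophage monocyte-derived genes did not stand apart (0.09, percentile 93.6). Fibroblast immediate early genes stood high (0.35, percentile 100), and T cell activation genes (0.41, percentile 100) too. Over the 77 pairs, 23 stood high and 12 low. Foxo1 over all kept cells had a ratio of 0.977 and in fibroblasts of 1.00.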

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

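The tests with the 50% mitochondrial limit, within each macrophage cluster, without 1 fibroblast cluster and without the top cell of a named gene were chosen only after the results were seen, and so was the rule that calls a list reversed when it stood apart and then changed sign or stood apart on the other side. A ratio is called reversed only where its main interval excludes no difference and the alternative lies on the other side. No paired analysis was possible because each group is 1 library and the comparisons come from no test. Over all alternatives, 290 of 296 share ratios, 308 of 308 Foxo1 ratios, 642 of 654 named-gene ratios and 1936 of 1968 list medians were not reversed. Of the share ratios 28 lay outside the counting interval of the main value without reversing, of the Foxo1 ratios 22 and of the named-gene ratios 142. Of the list medians, 116 no longer stood apart without reversing, and 127 stood apart only in the alternative. A list that did not stand apart in the main run could not be called reversed, so the count of lists not reversed overstates how stable they were. Foxo1 ratios whose main interval includes 1 did turn in some alternatives. In the second comparison that of smooth muscle cells went from 1.18 to 0.932 with each cell classed singly and 0.828 after thinning, that of macrophages from 1.14 to 0.942 with the 10% limit and that of endocardial cells from 0.902 to 1.06 with each cell classed singly. The cause of most differences was not tested. No scaling brought the median log2 ratio of all genes in a main class past 0.1 on either side.

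With the 10% limit, the fibroblast Foxo1 ratio of HFpEF-scr over Control was 0.964 and the fibroblast share ratio 1.01. List medians of that comparison were 0.064 for macrophage glycolysis, -0.043 for macrophage oxidative stress, -0.017 for fibroblast immediate early genes, and -0.068 and -0.63 for erythrocyte and neutrophil transcripts in fibroblasts and macrophages, and Spp1 was at -0.60. For the library labelled HFpEF-FoxO1-sh over HFpEF-scr, share ratios were 0.502 for B cells, 0.840 for endocardial, 0.796 for mesothelial and 0.165 for proliferating cells. Glycolysis medians were -0.062 in fibroblasts and -0.015 in macrophages, and Atp13a3 was at 0.089. Of 35 lists read, 10 stood high and 7 low in the first comparison, and of 37 in the second 10 stood high and 10 low.

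With the 50% limit, a cluster led by Rgs5 with endothelial markers was named pericyte, so endothelial values also rest on another class make-up. The endothelial share ratio of HFpEF-scr over Control was 0.926. Endothelial medians there were 0.68 for MHC class II, 0.11 for cholesterol, 0.0087 for oxidative phosphorylation, 0.075 for senescence, 0.018 for proliferation, 0.12 for cardiac rhythm and 0.70 for erythrocyte and neutrophil transcripts, and the macrophage glycolysis median was 0.068. In the second comparison the share ratios were 0.868 for B cells and 1.56 for pericytes, a class that then took in a cluster with endothelial markers, the endothelial medians 0.025 for interferon and 0.15 for MHC class II genes, the B cell list median 0.014 and Timp1 at -1.38. Without the top cell Timp1 was at -0.62.

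With each cell classed singly, share ratios of HFpEF-scr over Control were 0.75 for endocardial cells, 1.02 for fibroblasts, 1.78 for monocytes and 0.679 for pericytes. List medians were -0.056 for interferon, 0.025 for glycolysis and 0.031 for erythrocyte and neutrophil transcripts in macrophages, -0.12 for contractile genes in pericytes and 0.68 for erythrocyte and neutrophil transcripts in endothelial cells, and Igfbp3 was at 0.25. In the second comparison, share ratios were 0.375 for monocytes, 1.4 for pericytes and 0.490 for proliferating cells. Medians were 0.018 for macrophage glycolysis and 0.099 for pericyte immediate early genes, with Timp1 at -0.81, Igfbp3 at -0.015 and Sfrp2 at -0.55.

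Thinning to 1000 UMIs left out 16 cells of Control, 36 of HFpEF-scr and 45 of the library labelled HFpEF-FoxO1-sh. Foxo1 ratios were then 1.69 in endothelial cells for HFpEF-scr over Control, and 0.593 in endothelial cells, 1.18 in fibroblasts and 1.54 in macrophages in the second comparison. Medians of the first comparison were -0.11 for interferon, 0.014 for cholesterol, 0.038 for glycolysis, -0.099 for senescence and 0.27 for proliferation in macrophages, -0.074 for oxidative phosphorylation and -0.13 for cardiac rhythm in endothelial cells, and -0.038 for immediate early genes in pericytes. In the second they were 0.093 for the unfolded protein response in fibroblasts, and 0.052 for cholesterol and -0.15 for cardiac rhythm in endothelial cells, with Timp1 at -2.08. High and low lists numbered 7 and 7 in the first comparison and low lists 9 in the second.

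Within the cluster led by H2-Eb1 and Cx3cr1, medians of HFpEF-scr over Control were -0.090 for inflammatory, 0.097 for glycolysis and -0.024 for resident genes, and the resident median of the second comparison was -0.039. Within the cluster led by Timd4 and Folr2 they were 0.0023 for interferon and -0.014 for glycolysis, with Spp1 at -1.12, and in the second comparison 0.084 for glycolysis and -0.032 for monocyte-derived genes, with Spp1 at 0.87.

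Without doublet removal, the medians were -0.13 for endothelial MHC class II and 0.075 for macrophage glycolysis in the first comparison and 0.010 for pericyte immediate early genes in the second. Macrophage glycolysis was at 0.0467 with at least 1000 UMIs, where Timp1 was at -0.99, and at 0.0467 with resolution 0.5, where the proliferating class also held the dendritic cells and its share ratio was 0.608. With resolution 2.0 it was -0.010 in the first comparison and 0.048 in the second. With at least 100 UMIs per member, endothelial cardiac rhythm was at 0.057 and -0.080. After subtraction of free RNA, endothelial medians of the second comparison were -0.0099 for the unfolded protein response, -0.0022 for immediate early genes and -0.089 for cardiac rhythm. The correlations across genes were -0.495, -0.395, -0.543 and -0.401 in fibroblasts, macrophages, endothelial and smooth muscle cells with at least 200 UMIs, and -0.625, -0.566, -0.619 and -0.587 with UMIs unsplit.

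Some values could not be had, as too few cells or members were left or a cluster joined more than 1 class. With the 10% limit monocytes shared a cluster with neutrophils and no cluster was named pericyte, so the share ratios of monocytes and pericytes have no test with that limit. Foxo1 was missing there in monocytes, pericytes, platelets, Schwann, endothelial, B, T and natural killer cells, lists in endothelial cells, pericytes, B, T and natural killer cells, 2 macrophage lists, and the named endothelial genes of HFpEF-scr over Control. With resolution 0.5 dendritic cells shared a cluster with proliferating cells and natural killer cells with T cells, so the share ratios and Foxo1 of dendritic and natural killer cells were missing, as were natural killer and pericyte lists and Foxo1 in pericytes. Thinning, the minimum of 100 UMIs, free RNA, single classing and the Timd4 cluster left out a few lists, mostly erythrocyte and pericyte lists and endothelial MHC class II.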

Other observations

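The tests of the B cell and pericyte shares, of the monocyte share with the 50% mitochondrial limit and against leftover blood, and of handling in the immediate early genes were chosen only after the results were seen. So was the reading of lists in smooth muscle cells, a class they were not fixed for.

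In smooth muscle cells, cholesterol genes did not stand apart in HFpEF-scr over Control (0.08, percentile 85.6) and stood low in the library labelled HFpEF-FoxO1-sh over HFpEF-scr (-0.51, percentile 0), with 7 of 21 lower, such as Sqle (10.7 against 20.7 CPM). Interferon genes went from 0.27 (percentile 100) to -0.16 (percentile 1.73). Cells classed as cardiomyocytes, 43, 38 and 63 in Control, HFpEF-scr and the library labelled HFpEF-FoxO1-sh, formed a cluster led by Sln, Nppa, Myl4 and Myl7. They held 6, 9 and 17 UMIs of Foxo1, too few to say whether it was lower in the cells that the strainer removes. Whether these cells stand for the removed ones was not tested. Foxo3, a related factor, had a ratio of 1.04 (0.994 to 1.09) between the last 2 libraries over all kept cells.

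B cells and pericytes had higher shares in the library labelled HFpEF-FoxO1-sh than in HFpEF-scr. With the 50% limit the B cell ratio was 0.868 (0.799 to 0.943), so the 20% limit, which removes B cells unequally, may be the whole source of the B cell difference. The pericyte ratio was still 1.56 (1.39 to 1.75) there. The 50% limit also removes barcodes unequally, as 30.5% of all barcodes in HFpEF-scr and 16.0% in the library labelled HFpEF-FoxO1-sh lay over it. This test therefore cannot decide whether unequal loss at a mitochondrial limit is the whole cause of the pericyte difference. The class make-up differed as well at that limit, as a cluster with endothelial markers joined it with 221 cells in HFpEF-scr and 166 in the library labelled HFpEF-FoxO1-sh, while the cluster led by Kcnj8 held 263 and 558. Dissociation yield was not tested for either, and a biological difference between the vectors stays open, untested.

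The monocyte share was higher in HFpEF-scr than in the other 2 libraries. With the 50% limit the ratio over Control was 2.71 (2.20 to 3.36), which argues against the 20% limit. The B cell ratio of 1.03 (0.947 to 1.11) lay below it by more than the intervals. That argues against more leftover blood of unchanged make-up as the whole cause. The erythroid ratio of 1.51 (1.30 to 1.76) cannot gauge leftover blood. Red blood cells were lysed, and the main erythroid cluster at that limit had a median of 7905.5 UMIs, as deep as nucleated classes. The smaller one, with 8735.5 UMIs, had 8 macrophage markers among its top 50 genes, so the class is not red blood cells alone. Neutrophils were higher at 1.90 (1.55 to 2.33), an interval that overlaps that of monocytes. Leftover blood therefore stays open as part of the difference, and blood of another make-up was not tested. With each cell classed singly the monocyte ratio was 1.78 (1.47 to 2.16), and its interval reaches under the bound of 1.5 set beforehand, so the naming of clusters stays open. A biological difference between the diets stays open, untested, since diet, vector and library differ together and 1 library per group cannot separate them.

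Immediate early genes were higher in fibroblasts of the library labelled HFpEF-FoxO1-sh than in HFpEF-scr, with a median of 0.39. With the 10% limit it was 0.24 and without the cluster led by Il6 and Cxcl1 0.20, each between the bounds set beforehand, so RNA quality and that cluster stay open as part of the cause. The list stood at percentiles of 100, 100 and 99.6 in fibroblasts, macrophages and endothelial cells and 4.28 in smooth muscle cells, which leaves handling of 1 library open, since smooth muscle did not pass the lower bound of 2.5. In pericytes, outside the 4 classes of that test, it stood low (-0.20, percentile 0.54), but its median was 0.10 with each cell classed singly and 0.01 without doublet removal, so these 54 HFpEF-scr cells do not exclude handling. A biological difference between the vectors was not tested. Foxo1 was not lower over all kept cells of that library, so no direction of FoxO1 can be drawn from this list.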
